A study of Rattus norvegicus with 15 samples.

How the data were processed

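RNA of 15 samples of H9c2 cells was sequenced, 3 samples in each of 5 groups, after extraction with TRIzol and library preparation with an NEBNext Ultra RNA kit, per the labels. The labels carry the genotype tag WT for the cells. The deposited table gives 1 FPKM column per library, per the file headers. Trimmomatic, HISAT2, featureCounts and the genome build Rnor_6.0 are named in the submitters' processing notes, without versions or parameters. The step that turned counts into FPKM and any normalization between libraries are not given in the sources used here. Low values were compared between libraries for steps of whole reads, and none could be recovered (the most common ratio held 1.93% of 570 low genes between con replicates 1 and 2). Read depth is therefore unknown, no counting interval was computed, and no count model was used. The labels do not say whether the 3 samples of a group came from separate cultures or days. The replicates may be technical, and the p-values measure the spread between these samples.

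The table held 19344 entries. Of these, 16 exact duplicates were removed, which left 19328. No symbol was given for 1319 entries, 2 symbols had turned into dates, and 204 symbols stood on more than 1 entry (446 entries). Genes with FPKM of 1 or more in at least 3 of the 15 libraries were tested, 11288 in all, 10571 of them with a symbol. A linear model with a mean per group was fitted to log2(FPKM + 1) of all 15 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, 10 residual degrees of freedom). All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Reads shared between near-identical copies of a gene, or between overlapping or antisense genes, cannot be told apart in these values, so members of multigene families such as ribosomal protein genes are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

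The 4 main comparisons were DOX against con and each addition against DOX. The 6 secondary ones, each addition group against con and the addition groups against each other, are given mainly as counts. The model, the comparisons, most alternatives, the rule for naming genes and 30 gene lists were fixed before the data were examined. The 26 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation. Some genes stand on more than 1 list, so the lists are not independent. Of the genes fixed for a list, those shared with others were 8 of 20 for ferroptosis and 6 of 25 for the integrated stress response. They were 5 of 24 for NRF2 targets and 5 of 32 for p53 targets. The named genes of a main comparison were the 5 largest rises and 5 largest falls among called genes with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between the 3 libraries of either group. For each list that camera called, or with at least 5 called members making up 25% or more of its tested members, the 3 called members with the largest change were added (the member with the smallest p where none was called), up to 30 genes. Markers of doxorubicin action and oxidative stress fixed in advance completed the rule, and a gene named in 1 comparison may be given in another. Some listed genes were not analysed here, and some genes the rule takes are not reported here.

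Genes moved back were counted as those called in DOX against con and called with the opposite sign with an addition. Since the DOX libraries enter both contrasts, unchanged groups were simulated against them in 50 draws, and the overlap of independent lists and the covariance of fold changes were computed, the covariance with different DOX libraries on each side after the counts were seen. The share of the doxorubicin change that remained is the median over genes of the addition group's log2 difference from con divided by that of DOX. Alternatives were a pseudocount of 0.1, a filter at 5 FPKM and none, median scaling, quantile normalization, only the groups compared in the fit, no intensity trend, the replicate number as a block, a minimum change of 2-fold, an estimated correlation in camera, and each library left out in turn. Array weights and leaving out DSI+DOX replicate 3 for comparisons without DSI+DOX were added after the data were seen. Every split of the 6 libraries of a comparison into groups of 3 was also fitted.

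The fit was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 11288. For DOX against con it recovered 50% of the smaller and 94% of the larger changes with 13 false calls, and for AXT+DOX against DOX 54% and 93% with 9. With the deviation of DSI+DOX replicate 3 added to the simulated data, it recovered 34% and 80% for DOX against con and 27% and 88% for AXT+DOX against DOX. Array weights on the same simulated data recovered 53% and 93% for DOX against con and 51% and 92% for AXT+DOX against DOX. Each gene's simulated spread came from the fit of all 15 libraries and so already held the deviation of DSI+DOX replicate 3. Adding that deviation counted it again, so recovery with it may be lower than in the real fit. Recovery before it was added is not that of a fit lacking this library. In both comparisons camera called the 1 simulated list shifted by 0.3 and 0 of the other 25. The simulated spread was drawn separately for each gene, with no correlation between genes. How camera, the gene calls and array weights do where genes correlate was therefore not tested.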

Results

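Messenger RNA of H9c2 cells was profiled by RNA sequencing in 15 libraries, 3 for each of 5 groups. H9c2 is a myoblast line derived from embryonic rat heart. It divides in culture and can form multinucleate fibres of skeletal muscle type. The control group (con) received phosphate-buffered saline. The DOX group received 2 µM doxorubicin, an anthracycline that intercalates into DNA and traps topoisomerase II on it, for 24 h. The other groups received an addition 4 h before the same dose. It was 50 µL of danshen injection, a preparation of the root of Salvia miltiorrhiza, diluted 1 in 20 (DSI+DOX), 5 µM of the carotenoid astaxanthin (AXT+DOX) or 10 µM of the flavone diosmetin (DMT+DOX). No group received an addition without doxorubicin, so an effect of an addition on the cells cannot be separated here from an effect on their response to doxorubicin.

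The values are FPKM and the read depth is unknown, so no counting interval could be given. The FPKM of a library summed to between 433383 and 468608 in 14 libraries and to 548227 in DSI+DOX replicate 3. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were at least 0.991 between replicates of con, DOX, AXT+DOX and DMT+DOX. In the DSI+DOX group the correlation was 0.995 between replicates 1 and 2, while replicate 3 reached 0.953 and 0.963 with them. Ribosomal protein genes of the fixed list took 8.10% of the FPKM in DSI+DOX replicate 3 and from 4.81% to 5.79% in the other libraries. Of 11288 genes tested, 98 were over 2-fold higher and 882 over 2-fold lower in it than in the mean of replicates 1 and 2.

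DOX against con gives the response to doxorubicin itself. Genes of muscle differentiation, cell division and cholesterol synthesis fell, and genes of the integrated stress response, the p53 pathway and NF-kB inflammation rose. The deepest fall was in Myog, which encodes the muscle transcription factor myogenin, from 93.9 ± 4.03 to 2.38 ± 0.20 FPKM (SD, n = 3; log2 fold change -4.81 ± 0.11 (SE), adjusted p = 1.14e-11). The largest rise was in Lcn3, a lipocalin gene, from 0.445 ± 0.391 to 46.8 ± 3.16 FPKM (log2 fold change 5.08 ± 0.23 (SE), adjusted p = 1.94e-09). Mdm2, a p53 target that encodes the ubiquitin ligase of p53, rose from 68.4 ± 1.46 to 248 ± 17.7 FPKM, and Cdkn1a, the gene of the cell cycle inhibitor p21, from 111 ± 2.25 to 289.6 ± 8.34. Top2a, the gene of topoisomerase II alpha, fell from 33.3 ± 2.26 to 10.2 ± 0.621 FPKM. Slc4a11, a membrane transporter gene, rose from 0.254 ± 0.10 to 16.3 ± 0.929 FPKM.

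Of 16 tested skeletal myogenesis genes, 12 fell and 2 rose (2 higher and 12 lower adjusted over the list alone), with a median log2 fold change of -1.35 (camera adjusted p = 1.71e-08). Besides Myog, Mybph, a myosin-binding protein gene, changed by -2.94 and Acta1, the skeletal actin gene, by -2.79. Among 12 cardiac muscle genes, 6 fell and 1 rose (2 higher and 6 lower adjusted over the list alone), with a median of -0.39 (adjusted p = 0.00285). Those that fell included Tnnt2, the cardiac troponin T gene (-1.32), and Myl4, an atrial myosin light chain gene (-1.42). Of 6 hypertrophy markers, 3 fell and 2 rose (2 higher and 4 lower adjusted over the list alone), and that list did not pass its test (adjusted p = 0.0666). Dclk1, a doublecortin-like kinase gene (-2.67), and Aqp1, which encodes a water channel (-2.51), were also among the 5 largest falls.

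Of 29 mitosis genes, 28 fell and 1 rose (1 higher and 28 lower adjusted over the list alone), with a median of -1.19 (adjusted p = 6.49e-21). Ccnb1, the cyclin B1 gene, fell from 39.3 ± 0.883 to 9.84 ± 0.812 FPKM, and Plk1, a mitotic kinase gene, from 35.2 ± 1.05 to 9.31 ± 0.478. Of 30 DNA replication genes, 27 fell and 2 rose (2 higher and 27 lower adjusted over the list alone), with a median of -0.96 (adjusted p = 2.87e-18). Mcm6, of the replicative helicase, changed by -1.90 and Tk1, the thymidine kinase gene, by -1.80. Homologous recombination genes fell in 13 of 21 cases and rose in 1 (1 higher and 14 lower adjusted over the list alone), among them Exo1 (-1.62). This list's median was -0.58 (adjusted p = 2.97e-08, and adjusted p = 0.0685 with an estimated correlation). Cholesterol synthesis genes fell in 22 of 23 cases (0 higher and 22 lower adjusted over the list alone), with a median of -0.87 (adjusted p = 2.33e-15). Hmgcs1, the gene of an early synthase of that pathway, fell from 76.4 ± 1.56 to 31.1 ± 1.07 FPKM.

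Of 23 integrated stress response genes, 18 rose and 0 fell (18 higher and 0 lower adjusted over the list alone), with a median of 1.15 (adjusted p = 6.24e-13). Trib3, an ATF4-induced pseudokinase gene, rose by 3.23 and Ddit3, which encodes the transcription factor CHOP, by 2.88. Of 28 p53 targets, 19 rose and 1 fell (19 higher and 1 lower adjusted over the list alone; adjusted p = 2.21e-09), with Gadd45a at 2.49 and Plk2 at 1.98. NF-kB inflammation genes rose in 12 of 14 cases (12 higher and 1 lower adjusted over the list alone; adjusted p = 3.53e-08). Il6, an inflammatory cytokine gene, rose by 2.30 and Cxcl1, a neutrophil chemokine gene, by 1.95. NRF2 targets rose in 14 of 22 cases and fell in 3 (14 higher and 3 lower adjusted over the list alone; adjusted p = 7.86e-05). Those that rose included Slc7a11, the cystine transporter gene (2.48), Hmox1, the haem oxygenase gene (1.37), and Nqo1, a quinone reductase gene (1.24). Autophagy and lysosome genes rose in 17 of 22 cases (18 higher and 0 lower adjusted over the list alone; adjusted p = 1.27e-05), with Sqstm1, the gene of the autophagy receptor p62, at 1.46. Immediate early genes rose in 11 of 19 cases and fell in 3 (11 higher and 3 lower adjusted over the list alone; adjusted p = 0.000711). Interferon response genes rose in 8 of 16 and fell in 1 (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.0125), with Irf7, an interferon regulatory factor gene, at 1.80.

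Extracellular matrix genes fell in 12 of 26 cases and rose in 3 (3 higher and 12 lower adjusted over the list alone; adjusted p = 0.000829, and adjusted p = 0.191 with an estimated correlation). Glycolysis genes fell in 7 of 15 cases and rose in 2 (2 higher and 8 lower adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.125 with an estimated correlation). Ferroptosis genes rose in 8 of 17 cases and fell in 3 (8 higher and 4 lower adjusted over the list alone; adjusted p = 0.0466, and adjusted p = 0.123 with an estimated correlation). The ferroptosis call was lost without DOX replicate 3 (adjusted p = 0.0522) and without DSI+DOX replicate 3 (adjusted p = 0.0768). Bax, a pro-apoptotic gene, rose by 0.96. Gpx4, the gene of a lipid peroxide reductase, was at 0.57 ± 0.18 (adjusted p = 0.0236). Of 30 ribosomal protein genes 0 rose and 0 fell (0 higher and 0 lower adjusted over the list alone), and of 34 nuclear genes of oxidative phosphorylation 0 rose and 4 fell (0 higher and 4 lower adjusted over the list alone). These last lists did not pass camera (adjusted p = 0.790 and 0.227).

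limma called 4391 genes, 2802 higher and 1589 lower in DOX, of which 578 changed at least 2-fold. Higher calls made up 63.8% of them, against 52.7% (2306 higher and 2068 lower) after median scaling of the libraries and 51.6% (2450 higher and 2299 lower) after quantile normalization. Without DSI+DOX replicate 3, a setting chosen after the data were seen, the count was 6433. Gpx4 lost the call without con replicate 1 or 3 (adjusted p = 0.0631 and 0.0840) and without DOX replicate 1 or 3 (adjusted p = 0.0767 and 0.0565). Its limma adjusted p was 4.71e-05 without DSI+DOX replicate 3, which is in neither group. camera called 16 of 26 lists, 12 of them also with an estimated correlation.

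**Figure D1:**
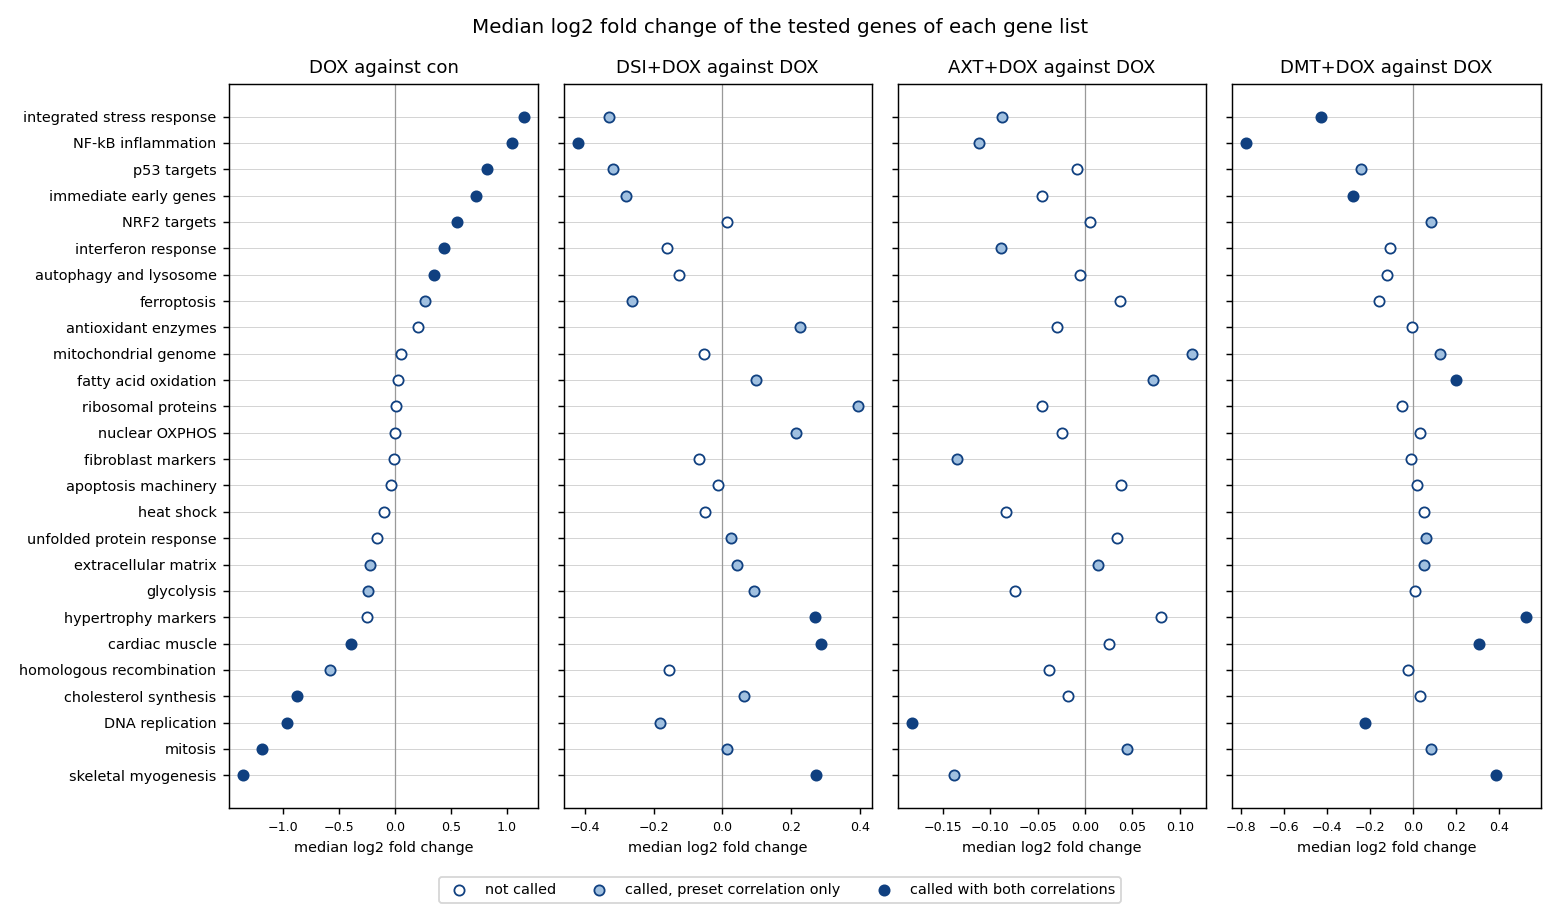
Median log2 fold change of the tested genes of 26 gene lists (points, horizontal axes on a scale of their own in each panel) in the 4 main comparisons. Filled points passed camera with both correlations and pale points with the preset correlation only; the skeletal myogenesis median is -1.35 in DOX against con, 0.27 in DSI+DOX against DOX and 0.38 in DMT+DOX against DOX.

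DSI+DOX against DOX asks what danshen injection changed in doxorubicin-treated cells. Muscle genes were higher and genes of NF-kB inflammation lower than with doxorubicin alone, while the lists of the integrated stress response and p53 targets were called lower only with the preset correlation (adjusted p = 0.0516 and 0.0765 with an estimated one). Slc4a11, which doxorubicin had raised, fell from 16.3 ± 0.929 to 4.37 ± 0.228 FPKM (SD, n = 3; log2 fold change -1.69 ± 0.08 (SE), adjusted p = 1.64e-07). Myog rose from 2.38 ± 0.20 to 6.94 ± 1.05 FPKM (log2 fold change 1.23 ± 0.11 (SE), adjusted p = 8.05e-05), against 93.9 FPKM in con. Hspb7, a small heat shock protein gene of muscle, rose from 25.9 ± 1.08 to 50.5 ± 4.26 FPKM. Polh, a translesion DNA polymerase gene and p53 target, fell from 14.1 ± 0.436 to 5.59 ± 1.36 FPKM, and Lcn3 from 46.8 ± 3.16 to 20.3 ± 8.27.

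Of 14 NF-kB inflammation genes, 9 fell and 0 rose (0 higher and 13 lower adjusted over the list alone), with a median of -0.42 (adjusted p = 1.84e-06, and adjusted p = 0.00447 with an estimated correlation). Tnfaip3, which encodes a feedback inhibitor of NF-kB signalling, changed by -1.04. Skeletal myogenesis genes rose in 6 of 16 cases and fell in 1 (8 higher and 1 lower adjusted over the list alone; adjusted p = 1.24e-09, and adjusted p = 0.00585 with an estimated correlation), with Acta1 at 1.00. Cardiac muscle genes rose in 4 of 12 cases (6 higher and 1 lower adjusted over the list alone; adjusted p = 2.07e-06, and adjusted p = 0.00447 with an estimated correlation), with Myl4 at 1.02. Hypertrophy markers rose in 3 of 6 cases (4 higher and 0 lower adjusted over the list alone; adjusted p = 1.52e-05, and adjusted p = 0.00585 with an estimated correlation). These were Acta1, Xirp1, an actin-binding muscle protein gene (0.71), and Ankrd1, a stretch-responsive muscle gene (0.35). In DSI+DOX replicate 3 the list medians lay 0.16 (skeletal myogenesis), 0.16 (cardiac muscle) and -0.08 (hypertrophy markers) from the mean of replicates 1 and 2 on the log2 scale. Without that library the medians in this comparison were 0.32, 0.30 and 0.33, against 0.27, 0.29 and 0.27 with it.

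Integrated stress response genes fell in 12 of 23 cases (0 higher and 18 lower adjusted over the list alone), with Chac1, a glutathione-degrading enzyme gene, at -0.52 (list adjusted p = 4.05e-07, and adjusted p = 0.0516 with an estimated correlation). p53 targets fell in 11 of 28 cases (0 higher and 15 lower adjusted over the list alone; adjusted p = 4.29e-06, and adjusted p = 0.0765 with an estimated correlation). Pmaip1, which encodes the apoptosis inducer NOXA, changed by -0.92 and Mdm2 by -0.53, while Cdkn1a was at -0.08 ± 0.06 (adjusted p = 0.370). Nqo1, a quinone reductase gene that doxorubicin had raised, rose further from 38.9 ± 1.28 to 54.8 ± 4.50 FPKM. With only the groups compared in the fit its adjusted p was 0.159. In that fit 40 of the 41 named genes called in this comparison lost the call. Immediate early genes fell in 7 of 19 cases and rose in 1 (1 higher and 11 lower adjusted over the list alone; adjusted p = 0.00637, and adjusted p = 0.0976 with an estimated correlation), with Fosl1, an AP-1 subunit gene, at -0.71. That list's adjusted p was 0.0661 without DSI+DOX replicate 1. Ferroptosis genes fell in 5 of 17 cases (0 higher and 8 lower adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.147 with an estimated correlation), and the adjusted p was 0.0583 without DOX replicate 3, 0.102 without DSI+DOX replicate 1 and 0.0521 without DSI+DOX replicate 2. DNA replication genes fell in 3 of 30 cases (0 higher and 8 lower adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.121 with an estimated correlation). Their list call was lost after median scaling (adjusted p = 0.124) and quantile normalization (adjusted p = 0.469), and the adjusted p was 0.0725 without DOX replicate 1, 0.191 without DSI+DOX replicate 1 and 0.0640 without DSI+DOX replicate 2.

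Fatty acid oxidation genes rose in 5 of 18 cases and fell in 1 (5 higher and 2 lower adjusted over the list alone; adjusted p = 0.000231, and adjusted p = 0.0516 with an estimated correlation), with Acaa2, a thiolase gene of mitochondrial beta-oxidation, at 0.61. In DSI+DOX replicate 3 this list's median lay 0.24 above replicates 1 and 2. Its median in this comparison was 0.10, and 0.04 without that library. Mitosis genes rose in 5 of 29 cases and fell in 2 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.000913, and adjusted p = 0.186 with an estimated correlation), with Ccnb1 at 0.53. Cholesterol synthesis had 1 of 23 members higher (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.000984, and adjusted p = 0.173 with an estimated correlation), and its adjusted p was 0.0544 without DSI+DOX replicate 1. Glycolysis had 1 of 15 members higher (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.00675, and adjusted p = 0.131 with an estimated correlation). Extracellular matrix genes (2 higher and 1 lower of 26; 2 higher and 1 lower adjusted over the list alone) tested higher than other genes with a median of 0.04 and a mean of -0.03 (adjusted p = 0.0249, and adjusted p = 0.348 with an estimated correlation). Unfolded protein response genes (1 higher and 2 lower of 21; 4 higher and 2 lower adjusted over the list alone) did so with a median of 0.02 and a mean of -0.03 (adjusted p = 0.0359, and adjusted p = 0.0976 with an estimated correlation). The adjusted p of the matrix list was 0.127 without DOX replicate 1, 0.216 without DSI+DOX replicate 1 and 0.0883 without DSI+DOX replicate 2, and that of the unfolded protein response list 0.0645 without DOX replicate 3, 0.0927 without DSI+DOX replicate 1 and 0.0812 without DSI+DOX replicate 2. After quantile normalization the glycolysis, extracellular matrix and unfolded protein response medians were -0.04, -0.11 and -0.03, with adjusted p = 0.770, 0.770 and 0.941.

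Ribosomal protein genes tested higher with a median of 0.39, 1 of 30 members called (0 higher and 0 lower adjusted over the list alone; adjusted p = 4.43e-16, and adjusted p = 0.173 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.21 and 1 of 34 called (0 higher and 0 lower adjusted over the list alone; adjusted p = 3.27e-10, and adjusted p = 0.175 with an estimated correlation). Antioxidant enzymes had a median of 0.23, with 1 higher and 1 lower of 19 (6 higher and 1 lower adjusted over the list alone; adjusted p = 6.51e-06, and adjusted p = 0.175 with an estimated correlation). Glrx, the glutaredoxin gene, rose from 37.1 ± 2.66 to 55.8 ± 4.34 FPKM. In DSI+DOX replicate 3 the medians of these 3 lists lay 0.77, 0.62 and 0.52 above replicates 1 and 2 on the log2 scale. Without that library their medians were 0.14, 0.04 and 0.05 in this comparison.

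limma called 889 genes, 166 higher and 723 lower, 19 of them at least 2-fold. All tested genes had a median of -0.11, which median scaling moved to -0.02 and quantile normalization to -0.00235. Higher calls made up 18.7%, 40.5% after median scaling (225 higher and 331 lower) and 46.6% after quantile normalization (351 higher and 402 lower). Relative to that shift, after quantile normalization, the list medians were -0.36 for NF-kB inflammation, -0.30 for the integrated stress response, 0.36 for skeletal myogenesis, 0.37 for cardiac muscle and 0.07 for hypertrophy markers. With only the 6 libraries of DOX and DSI+DOX in the fit, limma called 1 gene, and 1270 had an unadjusted p under 0.05. The count was 2531 and 1331 without DSI+DOX replicates 1 and 3, and 502, 366 and 542 without DOX replicates 1, 2 and 3. Of 41 named genes called, 13 lost the call when 1 library was left out (Tnnc2, Rpl11, Cox7b, Gdf15, Stc2, Lif, Ccl2, Tnnt2, Hand2, Txnrd2, Cdc25c, Fdps and Hmox1). They were 10, 10 and 12 genes without DOX replicates 1, 2 and 3 (adjusted p up to 0.128, 0.161 and 0.157) and 1 and 4 without DSI+DOX replicates 1 and 2 (up to 0.0524 and 0.0869). camera called 18 lists, 4 of them also with an estimated correlation.

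AXT+DOX against DOX asks the same of astaxanthin, and few genes changed. Postn, which encodes the matrix protein periostin, fell from 9.26 ± 0.831 to 3.41 ± 0.611 FPKM (SD, n = 3; log2 fold change -1.22 ± 0.11 (SE), adjusted p = 0.000449). Ptprv, a receptor-type phosphatase gene, changed by -0.82 ± 0.09 and Anxa8, an annexin gene, by -0.82 ± 0.09 (adjusted p = 0.00133 and 0.00133). Glrx rose from 37.1 ± 2.66 to 53.7 ± 1.67 FPKM (log2 fold change 0.52 ± 0.07 (SE), adjusted p = 0.00422), and Trim55, a muscle ubiquitin ligase gene, from 30.1 ± 1.57 to 42.6 ± 0.666 (log2 fold change 0.49 ± 0.06 (SE), adjusted p = 0.00435). Cat, the catalase gene, was at 0.49 ± 0.09 (adjusted p = 0.0192), and Nqo1 at 0.31 ± 0.07 (adjusted p = 0.0936). Without DSI+DOX replicate 3, a setting chosen after the data were seen, the limma adjusted p of Nqo1 was 0.0105.

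DNA replication genes were lower as a list, with 2 of 30 called (0 higher and 9 lower adjusted over the list alone), a median of -0.18 and adjusted p = 3.68e-09. It was the only list called here with an estimated correlation (adjusted p = 0.00199). Mcm3 (-0.46) and Mcm7 (-0.34), both of the replicative helicase, were the members called. Several lists tested lower with few or no members called. They were the integrated stress response (median -0.09, 0 of 23 called, 2 lower adjusted over the list alone; adjusted p = 3.67e-05), NF-kB inflammation (-0.11, 0 of 14, 2 lower adjusted over the list alone; adjusted p = 0.0318), the interferon response (-0.09, 0 of 16, 2 lower adjusted over the list alone; adjusted p = 0.0318), skeletal myogenesis (-0.14, 1 of 16, 3 lower adjusted over the list alone; adjusted p = 0.000358) and fibroblast markers (-0.14, 1 of 7, 1 lower adjusted over the list alone; adjusted p = 0.0156). Fatty acid oxidation tested higher (0.07, 0 of 18, 5 higher adjusted over the list alone; adjusted p = 0.00352). For each of these 6 lists the adjusted p = 0.0848 with an estimated correlation.

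Mitosis genes (0.04, 0 of 29 called, 0 higher and 0 lower adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.497 with an estimated correlation) and those of the mitochondrial genome (0.11, 0 of 13, 0 higher and 0 lower adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.356 with an estimated correlation) tested higher. Extracellular matrix genes tested lower with 3 of 26 called (0 higher and 4 lower adjusted over the list alone), a median of 0.01 and a mean of -0.08 (adjusted p = 0.0318, and adjusted p = 0.497 with an estimated correlation). After quantile normalization the mitosis, mitochondrial genome and extracellular matrix lists had adjusted p = 0.0980, 0.224 and 0.106. Among p53 targets 0 of 28 rose and 0 fell (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.592), and Mdm2 was at 0.00454 ± 0.09 (adjusted p = 0.997). With single libraries left out, the adjusted p of the interferon list was 0.0636 without DOX replicate 2, 0.0715 without DOX replicate 3, 0.0687 without DSI+DOX replicate 3, 0.0546 without AXT+DOX replicate 2 and 0.0517 without AXT+DOX replicate 3. That of mitosis was 0.156 without DOX replicate 3, 0.0857 without DSI+DOX replicate 3, 0.0502 without AXT+DOX replicate 2 and 0.219 without AXT+DOX replicate 3, and that of the mitochondrial genome 0.211 without DOX replicate 3 and 0.171 without AXT+DOX replicate 3. The matrix list had 0.221 without DOX replicate 3, 0.0821 without DSI+DOX replicate 3 and 0.0517 without AXT+DOX replicate 3, and NF-kB inflammation 0.0715 without DOX replicate 3.

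limma called 78 genes, 8 higher and 70 lower, 1 of them at least 2-fold, and 886 genes had an unadjusted p under 0.05. The count was 28, 12 and 23 without DOX replicates 1, 2 and 3, and 37, 21 and 21 without AXT+DOX replicates 1, 2 and 3. It was 372 (110 higher) without DSI+DOX replicate 3, which enters here through the pooled spread and the expression filter. Of 16 named genes called, Postn, Ptprv, Anxa8, Glrx and Trim55 held the call whichever of the 6 libraries was left out, and the other 11 did not (Dhrs3, Cat, Rgs2, Serpinb7, Eno3, Mcm3, Mcm7, Chrna1, Mfap5, Mmp2 and Tgfbi). The call was lost by 9, 11 and 7 of them without DOX replicates 1, 2 and 3 (adjusted p up to 0.149, 0.215 and 0.180) and by 8, 9 and 10 without AXT+DOX replicates 1, 2 and 3 (up to 0.117, 0.216 and 0.175). Without DSI+DOX replicate 3, which is in neither group, all 11 held the call (limma adjusted p up to 0.0075, in Tgfbi).

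DMT+DOX against DOX asks the same of diosmetin. The lists of NF-kB inflammation and the integrated stress response tested lower, and those of muscle and fatty acid oxidation genes higher, with both correlations. Ccl2, which encodes a monocyte-attracting chemokine, fell from 7.55 ± 0.812 to 1.05 ± 0.236 FPKM (SD, n = 3; log2 fold change -2.06 ± 0.14 (SE), adjusted p = 1.52e-06). Cxcl1 fell from 15.3 ± 1.12 to 3.56 ± 0.320 FPKM (log2 fold change -1.84 ± 0.10 (SE), adjusted p = 2.34e-07), where con had 3.22 ± 0.499. Nqo1, already raised by doxorubicin alone, rose from 38.9 ± 1.28 to 110.1 ± 7.21 FPKM (log2 fold change 1.48 ± 0.07 (SE), adjusted p = 1.05e-07), where con had 15.9 ± 0.875. Myog rose from 2.38 ± 0.20 to 8.42 ± 1.07 FPKM, Tnnc2, a fast skeletal troponin C gene, from 7.55 ± 1.10 to 20.3 ± 2.10 and Hspb7 from 25.9 ± 1.08 to 63.8 ± 0.863.

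Of 14 NF-kB inflammation genes, 11 fell and 0 rose (0 higher and 12 lower adjusted over the list alone), with a median of -0.78 (adjusted p = 5.36e-16). Of 23 integrated stress response genes, 16 fell and 0 rose (0 higher and 17 lower adjusted over the list alone), with a median of -0.43 (adjusted p = 1.18e-11). Slc7a5, an amino acid transporter gene, changed by -0.80 and Trib3 by -0.67. Immediate early genes fell in 9 of 19 cases and rose in 1 (3 higher and 11 lower adjusted over the list alone; adjusted p = 0.000680), with Maff, a small bZIP factor gene, at -1.21 and Fosl1 at -1.02. DNA replication genes, already lowered by doxorubicin as a list, fell in 10 of 30 cases (1 higher and 13 lower adjusted over the list alone; adjusted p = 4.81e-05), with Cdt1, a replication licensing factor gene, at -0.76. Fatty acid oxidation genes rose in 7 of 18 cases and fell in 1 (7 higher and 1 lower adjusted over the list alone; adjusted p = 1.25e-06), with Angptl4, a lipase inhibitor gene, at 1.24 and Ech1, of beta-oxidation, at 0.83. Skeletal myogenesis genes rose in 7 of 16 cases (10 higher and 1 lower adjusted over the list alone; adjusted p = 1.74e-06), cardiac muscle genes in 4 of 12 (6 higher and 1 lower adjusted over the list alone; adjusted p = 7.99e-05) and hypertrophy markers in 4 of 6 (4 higher and 0 lower adjusted over the list alone; adjusted p = 1.74e-06). These 8 lists passed camera with both correlations.

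p53 targets fell in 12 of 28 cases and rose in 1 (1 higher and 13 lower adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.172 with an estimated correlation). Pmaip1 changed by -0.66 and Aen, an apoptosis-enhancing nuclease gene, by -0.53, while Cdkn1a was at 0.10 ± 0.06 (adjusted p = 0.359). NRF2 targets tested higher with 2 of 22 called, Nqo1 among them, and with 1 higher and 0 lower adjusted over the list alone (adjusted p = 0.00143, and adjusted p = 0.0523 with an estimated correlation). Mitosis genes rose in 3 of 29 cases and fell in 1 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.00396, and adjusted p = 0.30 with an estimated correlation), with Cenpf, a kinetochore gene, at 0.67. Extracellular matrix genes (4 higher and 2 lower of 26; 4 higher and 2 lower adjusted over the list alone; adjusted p = 0.0308, and adjusted p = 0.412 with an estimated correlation) tested higher with a median of 0.05. Those of the mitochondrial genome (0 of 13 called; 0 higher and 0 lower adjusted over the list alone; adjusted p = 0.0212, and adjusted p = 0.30 with an estimated correlation) had a median of 0.13, and those of the unfolded protein response (2 higher and 1 lower of 21; 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.0463, and adjusted p = 0.0881 with an estimated correlation) a median of 0.06. The matrix list had adjusted p = 0.156 and the mitochondrial genome list 0.495 after quantile normalization, and the unfolded protein response list 0.0508 after median scaling. With single libraries left out, the matrix list had 0.115 without DOX replicate 1, 0.0522 without DOX replicate 2, 0.0702 without DMT+DOX replicate 1 and 0.0508 without DMT+DOX replicate 2. The mitochondrial genome list had 0.0832 without DOX replicate 3 and 0.0508 without DMT+DOX replicate 2, and the unfolded protein response list 0.0559 without DOX replicate 2, 0.0832 without DOX replicate 3, 0.0505 without DMT+DOX replicate 2 and 0.0850 without DMT+DOX replicate 3.

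limma called 1181 genes, 331 higher and 850 lower, 55 of them at least 2-fold. Higher calls made up 28.0%, 44.8% after median scaling (459 higher and 565 lower) and 44.4% after quantile normalization (543 higher and 680 lower). The count was 734 and 777 without DOX replicates 2 and 3, 679 and 672 without DMT+DOX replicates 1 and 2, and 2821 without DSI+DOX replicate 3. Of the named genes given here, Mef2c, Myl4, Gdf15, Ccnb1 and Mdm2 lost the call when 1 library was left out. These were 4, 3 and 2 genes without DOX replicates 1, 2 and 3 (adjusted p up to 0.0890, 0.0809 and 0.0746) and 2, 5 and 4 without DMT+DOX replicates 1, 2 and 3 (up to 0.0828, 0.0721 and 0.0900). Without DSI+DOX replicate 3, which is in neither group, each of them held the call (limma adjusted p up to 0.00615, in Gdf15).

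**Figure D2:**
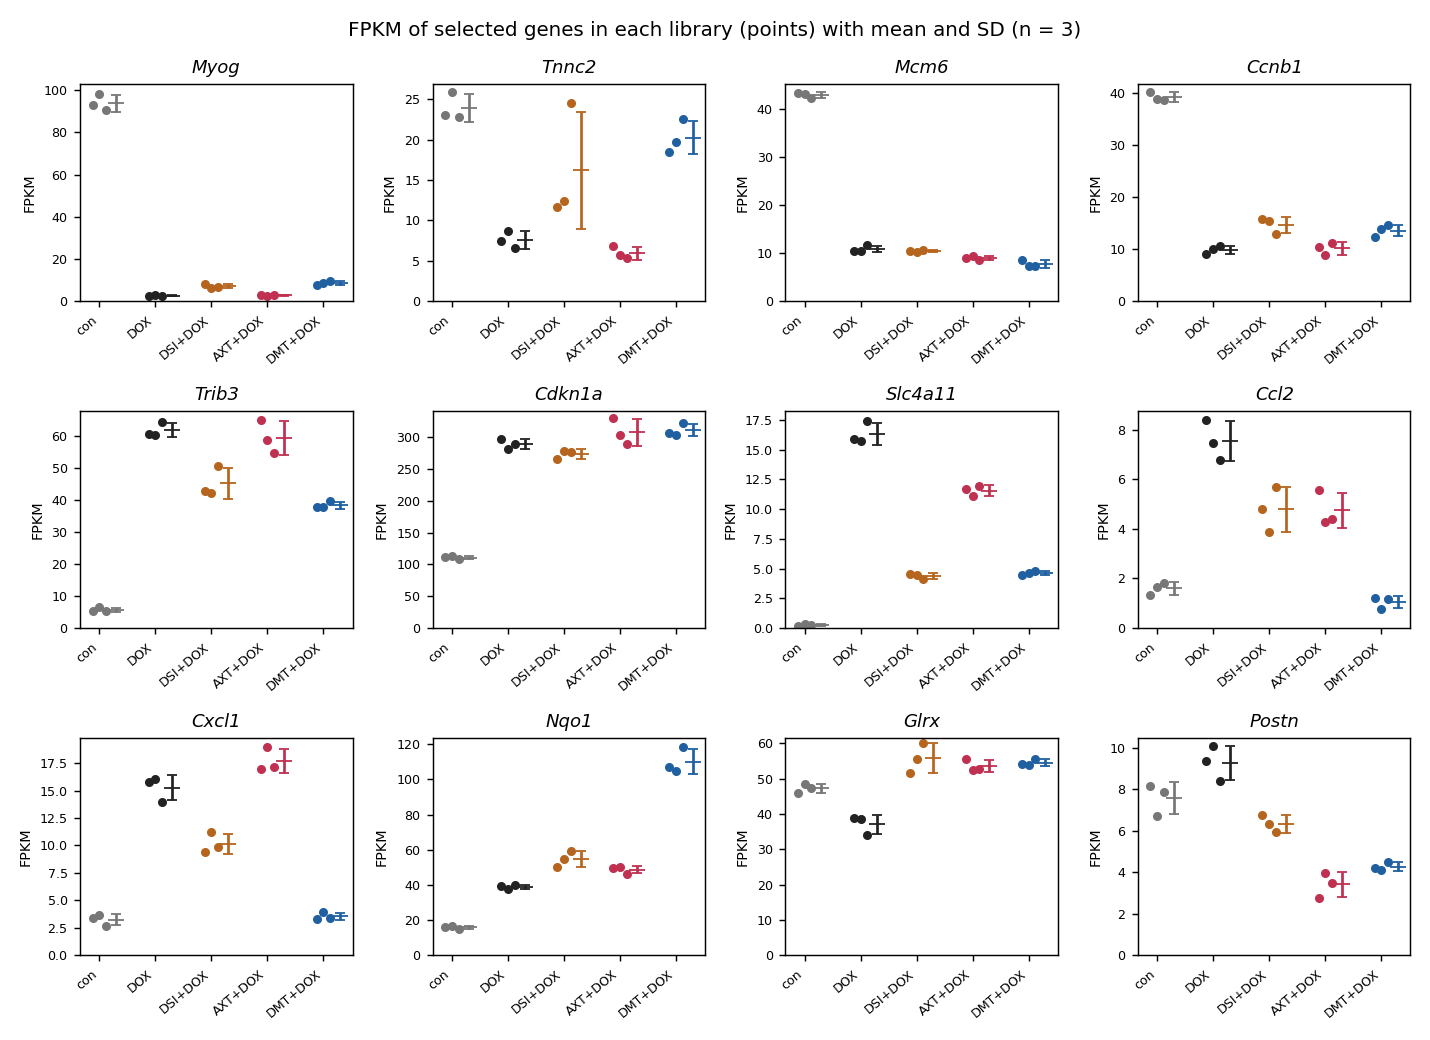
FPKM (vertical axes from 0) of 12 named genes in each of the 15 libraries (points, 3 per group), with the group mean and SD (bars). Ccl2 and Cxcl1 stand at 1.05 and 3.56 FPKM in DMT+DOX against 7.55 and 15.3 in DOX, and the group means of Cdkn1a lie between 274 and 311 FPKM in the 4 groups with doxorubicin.

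Set against the doxorubicin response, the changes with the additions ran mostly the opposite way. Of the 889 genes called with danshen injection, 708 had been called in the opposite direction in DOX against con and 27 in the same. Of those 708, 583 had risen with doxorubicin and fell with the addition. For astaxanthin the counts were 55 and 10 of 78, and for diosmetin 939 and 50 of 1181. Of the 939, 704 had risen with doxorubicin. The DOX libraries enter both contrasts with opposite sign. Independent lists of these sizes would share 203, 18.5 and 258 genes in opposite directions. These numbers leave the shared libraries out, so part of the excess may come from the shared libraries. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.0424 for danshen injection, -0.0293 for astaxanthin and -0.0751 for diosmetin, where shared libraries alone, with unchanged groups simulated against them (50 draws), gave -0.0117 on average. The differences were -0.0307, -0.0176 and -0.0634. The draws varied each gene and library separately. In the libraries outside DSI+DOX, deviations from the group means shared an axis that held 29.2% of their variance. The draws, also where used below, may therefore span too narrow a range. They also took each gene's spread from the fit of all 15 libraries, DSI+DOX replicate 3 included. The SD of the deviations from the group mean was 0.382 in that library and 0.0960 to 0.130 in the DOX libraries. Simulated covariances here and below may therefore lie too far from 0, and the differences above too near 0. The simulated shares may lie too far from 100%. Without DSI+DOX replicate 3 the counts of genes moved the opposite way were 1172, 263 and 2140. For danshen injection the count was 438 without DOX replicate 1, 334 without DOX replicate 2, 457 without DOX replicate 3 and 1086 without DSI+DOX replicate 1. After median scaling it was 465. With only the groups compared in the fit the count was 1 for danshen injection and 1758 for diosmetin. For astaxanthin the count was 33 without con replicate 1, 22 without DOX replicate 1, 9 without DOX replicate 2, 12 without DOX replicate 3, 27 without AXT+DOX replicate 1, 15 without AXT+DOX replicate 2 and 15 without AXT+DOX replicate 3. For diosmetin the count was 601 without DOX replicate 2, 569 without DMT+DOX replicate 1 and 562 without DMT+DOX replicate 2.

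Named genes show the extent. Slc4a11 stood at 0.254 FPKM in con, 16.3 in DOX, 4.37 with danshen injection and 4.63 with diosmetin. Trib3 stood at 5.73 in con, 61.8 in DOX and 38.4 with diosmetin. Among the 2802 genes raised by doxorubicin, the median share of the rise that remained was 66.5% ± 7.88 (SD of the 3 library values) with danshen injection, 87.7% ± 5.66 with astaxanthin and 61.2% ± 3.45 with diosmetin, against 97.4% in simulated unchanged groups. Among the 1589 genes lowered, 96.2% ± 24.6, 92.4% ± 2.62 and 75.9% ± 2.95 of the fall remained in the same order, against 95.6% when simulated. The gap between raised and lowered genes narrowed with scaling, to 77.6% and 85.2% for danshen injection and 65.5% and 69.5% for diosmetin after median scaling, and to 78.6% and 83.1%, and 65.3% and 69.7%, after quantile normalization. The danshen value for lowered genes was 123% in replicate 3, and 78.8% and 81.5% in replicates 1 and 2.

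**Figure D3:**
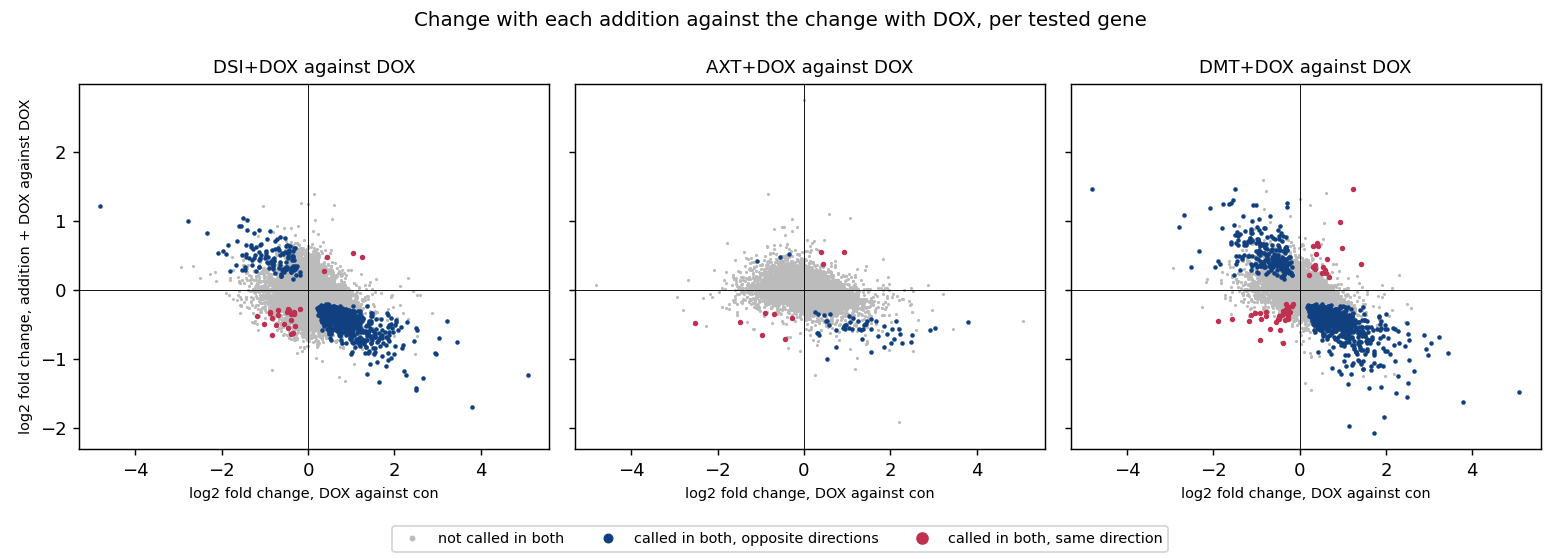
Log2 fold change of each of 11288 tested genes with an addition (vertical axis, against DOX) over its change with doxorubicin (horizontal axis, DOX against con), for the 3 additions. Blue points were called in both comparisons in opposite directions (708, 55 and 939 genes from left to right) and red points in the same direction (27, 10 and 50).

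The additions were also compared with each other. Danshen injection and diosmetin shared 539 calls of the same direction against DOX and 2 of opposite direction, where independent lists would share 59.3 of the same direction. Danshen injection and astaxanthin shared 50 (4.60 by independent lists), and astaxanthin and diosmetin 58 (5.51). The covariance of log2 fold changes across genes was 0.0270 for danshen injection and diosmetin, 0.0220 for astaxanthin and diosmetin and 0.00318 for danshen injection and astaxanthin, where shared DOX libraries alone gave 0.0118. Part of each overlap may come from those libraries. For danshen injection and astaxanthin the covariance lay below the lowest of the draws (0.0107). DSI+DOX replicate 3 enters this covariance and also widened the spread used in the draws, and no value without it was computed. The shared calls of these 2 additions were 50 of the same direction and 1 of opposite direction. Likeness between them beyond the shared libraries is therefore left open. In all, 557 genes were called in the same direction with at least 2 additions (1163 without DSI+DOX replicate 3, and 354, 275 and 338 without DOX replicates 1, 2 and 3), and 45 with all 3.

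Tested directly, 190 genes differed between DSI+DOX and DMT+DOX (39 higher and 151 lower), 1184 between DSI+DOX and AXT+DOX (282 higher and 902 lower) and 530 between AXT+DOX and DMT+DOX (291 higher and 239 lower). For DSI+DOX against AXT+DOX the all-gene median of -0.11 moved to 0.00383 with quantile normalization, which gave 520 higher and 535 lower, and median scaling gave 390 higher and 455 lower. For DSI+DOX against DMT+DOX these settings gave 297 (89 higher) and 197 genes (53 higher), 29.97% and 26.9% higher against 20.5% unscaled. Higher calls for AXT+DOX against DMT+DOX made up 54.9%, 37.0% after median scaling and 39.5% after quantile normalization. With only the 6 libraries compared in the fit, limma called 0 genes for DSI+DOX against DMT+DOX (917 at an unadjusted p under 0.05) and 0 for DSI+DOX against AXT+DOX (1493). For DSI+DOX against DMT+DOX the count was 2209 and 297 without DSI+DOX replicates 1 and 3, and 26, 28 and 47 without DMT+DOX replicates 1, 2 and 3. With the replicate number as a block it was 42. For DSI+DOX against AXT+DOX it was 4049 without DSI+DOX replicate 1, and 275 and 247 without AXT+DOX replicates 2 and 3. For AXT+DOX against DMT+DOX it was 1794 without DSI+DOX replicate 3, 287 and 295 without AXT+DOX replicates 2 and 3, and 271, 310 and 296 without DMT+DOX replicates 1, 2 and 3.

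Against con, 4718 genes differed in DSI+DOX (2317 higher and 2401 lower), 4010 in AXT+DOX (2563 higher and 1447 lower) and 2959 in DMT+DOX (1753 higher and 1206 lower). Myog, at 93.9 FPKM in con, stood at 6.94, 2.57 and 8.42 in these groups, and Cdkn1a, at 111 in con, at 274, 308 and 311. Higher calls in AXT+DOX against con made up 63.9%, 52.6% after median scaling (2076 higher and 1872 lower) and 51.5% after quantile normalization (2216 higher and 2088 lower). The count for DSI+DOX was 3143 without con replicate 3, and without DSI+DOX replicate 3 the counts for AXT+DOX and DMT+DOX were 6038 and 5089.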

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

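The tests of a mislabelled library, of the shared DOX libraries, of a weaker action of doxorubicin and of NRF2 activation were chosen only after the results they concern were seen, as was leaving out DSI+DOX replicate 3 where DSI+DOX is not compared and in the covariances, and the tests of NRF2 activation and of a mislabelled library were also changed after their first results were seen. Some genes, picked after their values were seen, changed in opposite directions with different additions, each by a test of the difference in limma (n = 3 per group). They were picked because limma called them in opposite directions against DOX, so a small p of the difference largely follows from that choice. The weakest of those calls was Id2 with danshen injection (limma adjusted p = 0.0475). Fam180a changed with danshen injection and astaxanthin by 0.55 and -0.65, a difference of 1.19 ± 0.08, adjusted p = 4.31e-06. With astaxanthin and diosmetin it changed by -0.65 and 0.92, a difference of -1.56 ± 0.08, adjusted p = 1.36e-07. C1qtnf3, with astaxanthin and diosmetin, changed by -0.61 and 0.64, a difference of -1.25 ± 0.11, adjusted p = 2.73e-05. Aqp1, a water channel gene, changed with the same pair by -0.47 and 0.33, a difference of -0.80 ± 0.09, adjusted p = 0.000128. Slpi, the gene of a secreted protease inhibitor, changed with danshen injection and diosmetin by 0.55 and -0.93, a difference of 1.48 ± 0.10, adjusted p = 2.22e-05. Id2, which encodes an inhibitor of bHLH factors, changed with that pair by -0.37 and 0.46, a difference of -0.82 ± 0.10, adjusted p = 0.00203.

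Genes that doxorubicin changed moved back with the additions (708, 55 and 939 genes with all libraries in the fit). With only the groups compared in the fit the danshen count was 1 and the diosmetin count 1758. Spread separate to each shared DOX library would give no covariance below 0 once different DOX libraries stood on each side. In all 3 such arrangements it stayed below 0, with values nearest 0 of -0.022 (danshen injection), -0.02 (astaxanthin) and -0.0643 (diosmetin). This argues against such spread as the whole source (the danshen mean was -0.0355, and -0.0600 without DSI+DOX replicate 3). An offset common to all 3 DOX libraries would still give a covariance below 0, so this test cannot decide on it. A uniformly weaker action of doxorubicin would raise the lists it lowered. The DNA replication list instead tested lower than other genes with astaxanthin and diosmetin (medians -0.18 and -0.22). The camera adjusted p was 0.00199 and 0.00874 with an estimated correlation. This shift of the DNA replication list argues against a uniformly weaker action for these additions. The test asked whether any of the lowered lists of mitosis, DNA replication, homologous recombination and cholesterol synthesis fell further. The mitosis list tested higher with both additions (medians 0.04 and 0.08), though not with an estimated correlation (camera adjusted p = 0.497 and 0.30). The other lists named were called with neither. Single members of the DNA replication list give little for astaxanthin with all libraries in the fit. Only Mcm3 and Mcm7 were called, and they lost the call in 6 and 5 of 6 fits with a library of the 2 groups left out. Without DSI+DOX replicate 3, limma called 0 of 30 members higher and 7 lower. Mcm3 and Mcm7 were among these 7 (adjusted p = 0.002 and 0.00569). For danshen injection the adjusted p of the DNA replication list was 0.121 and leaves a weaker action open. Nqo1, which doxorubicin raised, nevertheless rose further there (0.48 ± 0.07), and Cdkn1a was at -0.08 ± 0.06. An effect of the additions on the cells themselves may also give this pattern and was not tested, since no group received an addition alone.

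DSI+DOX replicate 3 stood apart from its group. A mislabelled library of another group is argued against: over genes that separated DSI+DOX replicates 1 and 2 from another group, taken higher and lower apart, its median position from that group (0) to DSI+DOX (1) was 0.517 or more, where libraries of those groups reached 0.248 at most, although single genes scattered (lower quartile -0.62 for the 304 genes higher than in DOX) and its correlations alone (0.965 with DOX replicate 1, 0.953 and 0.963 with its own group) did not decide. Admixed endothelial cells, leukocytes or epithelial cells are argued against, as far as a count of marker genes at 1 FPKM can tell. Fewer genes of any kind reached 1 FPKM in this library (10545) than in the others, so a small admixture could be missed. Its marker genes at 1 FPKM were 4, of endothelial cells (2 of 11), leukocytes (1 of 13) and epithelial cells (1 of 9). Another library had up to 5, and every library expressed 2, 1 and 1 of them. The most abundant, Egfl7, Cd14 and Krt8, lay between 9.38 and 15.9, 13.1 and 18.3, and 4.50 and 10.0 FPKM over all libraries, while fibroblast markers lay 0.38 above replicates 1 and 2 in the median (5 of 7 higher), and cells of that or any further type were not tested. A technical axis shared with the other groups is a candidate explanation, since across genes its deviation correlated at r = 0.755 (absolute value; genes are not independent replicates) with the first component of the residuals of the other 12 libraries, which held 29.2% of their variance.

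Nqo1 rose with diosmetin by 1.48. NRF2 activation is left open: 1 of 21 other tested NRF2 targets was called higher, a share that argued against it by the test as first written, but the test was changed after that result was seen, because 5 were called higher and 1 lower without DSI+DOX replicate 3. Activation of the aryl hydrocarbon receptor is a candidate explanation: 2 of 3 other tested targets of a list fixed beforehand were called higher, Ahrr (1.27 ± 0.10, limma adjusted p = 6.13e-06) and Cyp1b1 (0.64 ± 0.15, limma adjusted p = 0.0171), while Tiparp was at 0.21 ± 0.28. Cyp1b1 also stood at 59.5 ± 4.60 FPKM in AXT+DOX and 62.3 ± 3.65 in DMT+DOX against 39.6 ± 0.643 in DOX (SD, n = 3), and Cyp1a1, the classic target, had means of 0.0534 FPKM in DOX and 0.0237 in DMT+DOX.

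With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large cannot fall under 0.05, and the smallest possible is 0.1. In each case 1 of the 10 splits, the real one, gave a result that large. The real split and the highest other gave 4391 and 0 genes for DOX against con, 889 and 4 for danshen injection, 78 and 0 for astaxanthin and 1181 and 0 for diosmetin against DOX. Against con they gave 4718 and 0, 4010 and 1, and 2959 and 1 in that order. Between addition groups they gave 1184 and 0 (DSI+DOX against AXT+DOX), 190 and 0 (DSI+DOX against DMT+DOX) and 530 and 0 (AXT+DOX against DMT+DOX). For genes moved back the values were 708 and 1, 55 and 0, and 939 and 0. For lists they were 16 and 15, 18 and 7, 10 and 8, and 14 and 11 in the order of the main comparisons. Each of the other splits puts libraries of both groups on each side. Part of the real difference stays in it, and the spread within each side is widened. These splits are therefore no measure of calls without a change, for genes or for lists. The highest value of 15 lists cannot be read as false calls of camera.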

How the results depend on the processing

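Array weights, leaving out DSI+DOX replicate 3 for comparisons without DSI+DOX, and the left-out libraries for the shares kept were chosen only after the data were seen. Values of named genes under other settings counted as kept if they stayed on their side of the threshold, with their direction where called. A gene called in neither fit counted as kept whatever its sign. The kept values were 719 for DOX against con (11 lost the call, 5 gained it) and 591 for DSI+DOX against DOX (108 and 3). They were 397 for AXT+DOX (76 and 21) and 642 for DMT+DOX against DOX (32 and 10). Called lists kept direction and call in 261, 249, 127 and 218 values and lost the call in 11, 38, 43 and 20. Read depth is not known, so what it limits cannot be stated.

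With a pseudocount of 0.1, the genes called were 41 (AXT+DOX against DOX) and the genes moved back 23 (astaxanthin). With no filter, the genes called were 162 (AXT+DOX against DOX), the lists called 5 (AXT+DOX against DOX), the genes moved back 123 (astaxanthin) and the shares kept 58.2% (danshen injection, genes raised) and 55.6% (diosmetin, genes raised). With a filter at 5 FPKM, the genes called were 44 (AXT+DOX against DOX) and the genes moved back 27 (astaxanthin). With median scaling, the genes called were 556 (DSI+DOX against DOX), the genes moved back 465 (danshen injection) and the shares kept 77.6% (danshen injection, genes raised), 65.5% (diosmetin, genes raised) and 69.5% (diosmetin, genes lowered). With quantile normalization, the genes called were 297 (DSI+DOX against DMT+DOX) and the shares kept 78.6% (danshen injection, genes raised), 65.3% (diosmetin, genes raised) and 69.7% (diosmetin, genes lowered). With only the groups compared in the fit, the genes called were 1 (DSI+DOX against DOX), 2252 (DMT+DOX against DOX), 1613 (DSI+DOX against con), 5376 (DMT+DOX against con), 0 (DSI+DOX against AXT+DOX), 0 (DSI+DOX against DMT+DOX) and 1222 (AXT+DOX against DMT+DOX), the genes moved back 1 (danshen injection) and 1758 (diosmetin) and the overlap between additions 66. With array weights, the genes called were 8592 (DOX against con), 8777 (DSI+DOX against DOX), 6074 (AXT+DOX against DOX), 6009 (DMT+DOX against DOX), 8579 (DSI+DOX against con), 8086 (AXT+DOX against con), 6494 (DMT+DOX against con), 8188 (DSI+DOX against AXT+DOX), 5593 (DSI+DOX against DMT+DOX) and 4697 (AXT+DOX against DMT+DOX), the lists called 4 (AXT+DOX against DOX), the genes moved back 5377 (danshen injection), 3468 (astaxanthin) and 4475 (diosmetin), the shares kept 84.7% (astaxanthin, genes lowered) and the overlap between additions 6077. With a minimum change of 2-fold, the genes called were 578 (DOX against con), 19 (DSI+DOX against DOX), 1 (AXT+DOX against DOX), 55 (DMT+DOX against DOX), 403 (DSI+DOX against con), 446 (AXT+DOX against con), 262 (DMT+DOX against con), 19 (DSI+DOX against AXT+DOX), 5 (DSI+DOX against DMT+DOX) and 26 (AXT+DOX against DMT+DOX). With an estimated correlation, the lists called 4 (DSI+DOX against DOX), 1 (AXT+DOX against DOX) and 8 (DMT+DOX against DOX). The extracellular matrix list of DSI+DOX against DOX turned downward after quantile normalization (adjusted p = 0.770), and Top2a there, at -0.01 ± 0.17 (adjusted p = 0.960), was at 0.11 with array weights and was called there. A minimum change removes genes by construction. For the other settings the cause was not tested.

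With the replicate number as a block, the genes called were 569 (DSI+DOX against DOX), 31 (AXT+DOX against DOX), 735 (DSI+DOX against AXT+DOX) and 42 (DSI+DOX against DMT+DOX) and the genes moved back 22 (astaxanthin). Over all groups the numbers gave no sign of pairing. Deviations from the group means of same-numbered libraries correlated across genes between -0.54 and 0.52 in 30 pairs (8 above 0.1). Of 15 libraries, 2 correlated best with their own number. Between DSI+DOX and DMT+DOX the same-numbered values were 0.24, 0.34 and 0.52, although DSI+DOX replicate 1 reached 0.36 with DMT+DOX replicate 2. Pairing cannot be set aside for that comparison, where the count without a block was 190.

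With 1 library left out, the counts of genes called ranged over 3496 to 6433 (DOX against con), 366 to 2531 (DSI+DOX against DOX), 12 to 372 (AXT+DOX against DOX), 672 to 2821 (DMT+DOX against DOX), 3143 to 6291 (DSI+DOX against con), 3198 to 6038 (AXT+DOX against con), 2151 to 5089 (DMT+DOX against con), 247 to 4049 (DSI+DOX against AXT+DOX), 26 to 2209 (DSI+DOX against DMT+DOX), 271 to 1794 (AXT+DOX against DMT+DOX). Lists called ranged over 15 to 17 (DOX against con), 12 to 19 (DSI+DOX against DOX), 5 to 12 (AXT+DOX against DOX), 11 to 15 (DMT+DOX against DOX). Genes moved back ranged over 334 to 1172 (danshen injection), 9 to 263 (astaxanthin), 562 to 2140 (diosmetin). Shares kept ranged over 63.0 to 70.7 (danshen injection, raised), 79.5 to 107 (danshen injection, lowered), 84.3 to 89.5 (astaxanthin, raised), 86.6 to 94.6 (astaxanthin, lowered), 59.3 to 62.8 (diosmetin, raised), 75.0 to 77.5 (diosmetin, lowered), in percent, and the overlap between additions over 275 to 1163 (genes).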

Other observations

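The single genes of this part were chosen after their values were seen, all from lists fixed beforehand, with adjusted p from limma (n = 3 per group). The apoptosis machinery list moved both ways with doxorubicin (9 higher and 6 lower of 26 tested), with rises of Bcl2l1 (1.09 ± 0.06, adjusted p = 2.18e-08), which protects from apoptosis, and Fas (0.60 ± 0.06, adjusted p = 3.87e-06), a death receptor, and falls of Bmf (-0.69 ± 0.15, adjusted p = 0.00222) and Bcl2l11 (-0.46 ± 0.14, adjusted p = 0.0170), which promote it. Unfolded protein response genes were called both ways (4 higher and 9 lower of 21 tested), with the chaperones Pdia4 (-0.66 ± 0.06, adjusted p = 1.33e-06) and Hyou1 (-0.49 ± 0.08, adjusted p = 0.000200) lower and Herpud1 (0.96 ± 0.05, adjusted p = 1.22e-08) higher. Few heat shock genes were called (1 higher and 3 lower of 15 tested). Of the antioxidant enzymes (6 higher and 4 lower of 19 tested), Gpx1 (0.67 ± 0.16, adjusted p = 0.00489) and Prdx6 (0.64 ± 0.09, adjusted p = 6.64e-05) rose, and Prdx2 (-0.45 ± 0.13, adjusted p = 0.0131) fell. camera called none of these lists with doxorubicin (adjusted p = 0.837, 0.0810, 0.0666 and 0.397 in the order given).

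The interferon response list, which doxorubicin raised, was not called by camera with danshen injection (adjusted p = 0.109) or diosmetin (adjusted p = 0.123). Single members fell, 0 higher and 3 lower of 16 tested with danshen injection and 0 higher and 5 lower of 16 tested with diosmetin, and after median scaling 2 and 2 were called lower. Tap1 (1.87 ± 0.07, adjusted p = 3.48e-10), which carries peptides for antigen presentation, rose with doxorubicin and fell with danshen injection (-0.60 ± 0.07, adjusted p = 0.000213) and with diosmetin (-0.70 ± 0.07, adjusted p = 2.64e-05). Cxcl10 (-0.59 ± 0.16, adjusted p = 0.0364), a chemokine gene, fell with diosmetin. In 4 lists fewer than 5 genes were tested, and camera was not run on them.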
